A study of Mus musculus with 6 samples.

How the data were processed

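The data describe clear cells of the mouse epididymis, isolated by double sorting for EGFP from the caput, corpus and cauda of untreated transgenic mice aged 12 weeks, with 2 libraries per region and 12 epididymides per library, per the labels' protocols. RNA was isolated with a PicoRNA kit, libraries were made with the Clontech SMARTer v4 kit, and sequencing was on a HiSeq2500, per the labels' protocols. The authors deposited a file of read counts per gene for each library and a table of RPKM values for all 6. The submitters' processing notes name STAR, HTSeq and edgeR and the genome build mm9; versions and the annotation release are not given in the sources used here. The count files were made without regard to strand, per the name of each deposited file, so reads of overlapping or antisense genes cannot be told apart.

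The deposited counts are whole numbers that sum to different totals, and they entered the tests as deposited. Rows that name no gene were left out of library sizes and tests: reads in no feature were 6.67% to 9.48% of all records, ambiguous reads 1.39% to 1.83% and reads without a unique position 33.11% to 38.59%. Families of near-identical genes (beta-defensins, Wfdc, Klk1b, Gstm, MHC, Pcdhb, histone and ribosomal protein genes) lose reads at that step, and their values are uncertain to that extent. The deposited RPKM values are the same counts divided by the deposited gene length and by a library size scaled by 1 factor per library, which the values show to be 1.329 and 1.387 for caput, 0.957 and 0.925 for corpus, and 0.774 and 0.792 for cauda. The deposited length column (unit "other") gives bases per gene and was used for the check on gene length. The count files list 37583 genes, of which 37578 are in the RPKM table that gave the symbols; 24903 had a read. No symbol with the mt- prefix is in the table, so the list of mitochondrially encoded genes had 0 measured members. The reference annotation at hand was of another build, so no coordinates are given; its transcripts served only for GC content by gene identifier.

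Reads in genes came to between 18887128 and 24700717 per library. Replicates of a region differed by more than sampling noise, with a chi-square per degree of freedom of 17.18 in caput, 9.57 in corpus and 12.17 in cauda over genes with at least 10 reads, and each library was kept as its own sample. Each library is a pool, and the labels do not say that the 2 pools of a region are independent groups of mice, so p-values measure only the spread between these libraries. The 10 most abundant genes took 4.41% and 4.55% of the reads in caput, 18.93% and 19.86% in corpus, and 26.91% and 26.25% in cauda, and the TMM factors were 1.381 and 1.415, 0.946 and 0.911, and 0.761 and 0.78. Intervals and floors (3 counts over the group, 95% exact intervals) cover counting error only, since the reads carry no molecular identifiers.

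The main test was edgeR 4.0.16 (R 4.3.3): filterByExpr by region, TMM scaling, robust dispersions, and quasi-likelihood F tests on all 6 libraries with region as the only factor, which leaves 3 residual degrees of freedom. Tests are two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. A gene was highest in a region when it was called higher than in both others. Of the 31 gene lists, those other than the red blood cell list (1 measured member) and the mitochondrially encoded list (0) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over 87 tests, of which 22 were called; with an estimated correlation 0 were called by camera, and 4 at an unadjusted p under 0.05. With an estimated correlation camera is limited to the 3 residual degrees of freedom, so it could hardly call any list, and a call lost in that setting decides nothing. Camera compares a list with all other genes. Under library totals, which shift the bulk of the genes, a camera call or its direction is therefore relative to that bulk. For lists with a fold change from 0 to 3 reads the median rests on fitted values for those genes and is no bound.

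The design, the lists, the alternatives and the rule for the genes named were fixed before the data were examined. Per comparison the rule took the 8 called genes with the largest positive and the 8 with the largest negative fold change, with at least 10 CPM in the higher region and no overlap between the libraries of the regions. Predicted genes were passed over, and some genes that the rule took are not reported here. It added up to 3 called members of each list with the smallest adjusted p (or the 2 most abundant, as values), the genes Atp6v1b1, Foxi1, Aqp9, Krt5, Ptprc and Prm1 in every comparison, and the 5 genes highest in each region with the largest smaller fold change.

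The same steps were tested on simulated counts drawn from the real means and library sizes, with 200 of the 15816 genes changed. For caput against cauda, 23.9%, 56.7% and 80.3% of genes changed by 0.5, 1 and 2 log2 units were recovered, for corpus against cauda 11.9%, 58.2% and 72.7%, and for caput against corpus 19.4%, 53.7% and 69.7%. False calls made up 13.7%, 11.2% and 21.5% of the calls, so the error rate among calls can exceed the nominal one. The simulation changed far fewer genes than were called in the data, so neither these shares nor the recovered percentages carry over to the data. In 20 draws with no effect, at most 7, 8 and 9 genes were called. The alternatives tried were DESeq2 1.42.0 (its size factors, and its test), no filter and a stricter filter on low counts (5 CPM in 2 libraries), dispersions that are not robust, only the 4 libraries compared, the replicate number as a block, limma on log2(RPKM + 1) with and without a minimum of 1 RPKM and on log2(RPKM + 0.1) with it, a minimum log2 change of 1, a prior count of 0.5, and leaving out each library in turn. Library totals as the only scaling, and removal of a gene length trend (lowess, span 0.3), were added after seeing the data.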

Results

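RNA was sequenced from clear cells of the mouse epididymis, the duct in which sperm mature after leaving the testis. Clear cells are epithelial cells that secrete protons into the duct through the vacuolar proton pump (V-ATPase). They were collected by cell sorting from transgenic mice whose EGFP is driven by the promoter of Atp6v1b1, a V-ATPase subunit gene. The samples came from the caput, corpus and cauda, the proximal, middle and distal parts of the duct, with 2 libraries per region. Each library pooled 12 epididymides of mice aged 12 weeks. Reads assigned to genes came to 24700717 and 20724911 in the caput libraries, 18887128 and 21669090 in corpus, and 22593268 and 23532405 in cauda. Levels below are CPM, read counts relative to the TMM-scaled library size, as mean ± SD of n = 2 libraries. Fold changes are on the log2 scale ± SE, positive where the first region of a comparison is higher, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 15816 tested genes. The test itself gives no SE. It was derived as the absolute log2 fold change divided by the square root of the F statistic, and is approximate. The comparisons asked how the expression profile of clear cells depends on their place along the duct.

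Clear cell genes were present in every library, and most were more abundant in caput than in the other regions. Foxi1 (ENSMUSG00000047861), the transcription factor that specifies proton-secreting epithelial cells, measured 2287 ± 142 CPM in caput, 386 ± 2.88 in corpus and 177 ± 37 in cauda. Atp6v1b1 (ENSMUSG00000006269) measured 314 ± 18.7 CPM in caput, 59.3 ± 8.65 in corpus and 20.4 ± 5.35 in cauda; its promoter drove the reporter used for sorting, so its presence was selected for. Aqp9, a water and glycerol channel known from principal cells, ran the other way at 29.9 ± 11 CPM in caput, 244 ± 3.88 in corpus and 302 ± 5.71 in cauda. Krt5, a keratin of basal cells, measured 46.3 ± 12.2 CPM in caput, 8.54 ± 3.76 in corpus and 9.46 ± 3.98 in cauda, and Ptprc, the pan-leukocyte gene, 3.36 ± 1.48 CPM in caput, 2.44 ± 0.919 in corpus and 1.25 ± 0.858 in cauda. Prm1, a sperm chromatin gene, measured 7.16 CPM in caput 1 and 46.07 CPM in caput 2, against 0.104 ± 0.0679 in corpus and 0.0545 ± 0.0771 in cauda. In a test of all regions together, 11881 of the 15816 genes (75.1%) differed. The first principal component of log2 CPM held 65.1% of the variance and parted caput (-129.2 and -125.18) from corpus (39.47 and 40.26) and cauda (89.75 and 84.9).

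**Figure D1:**
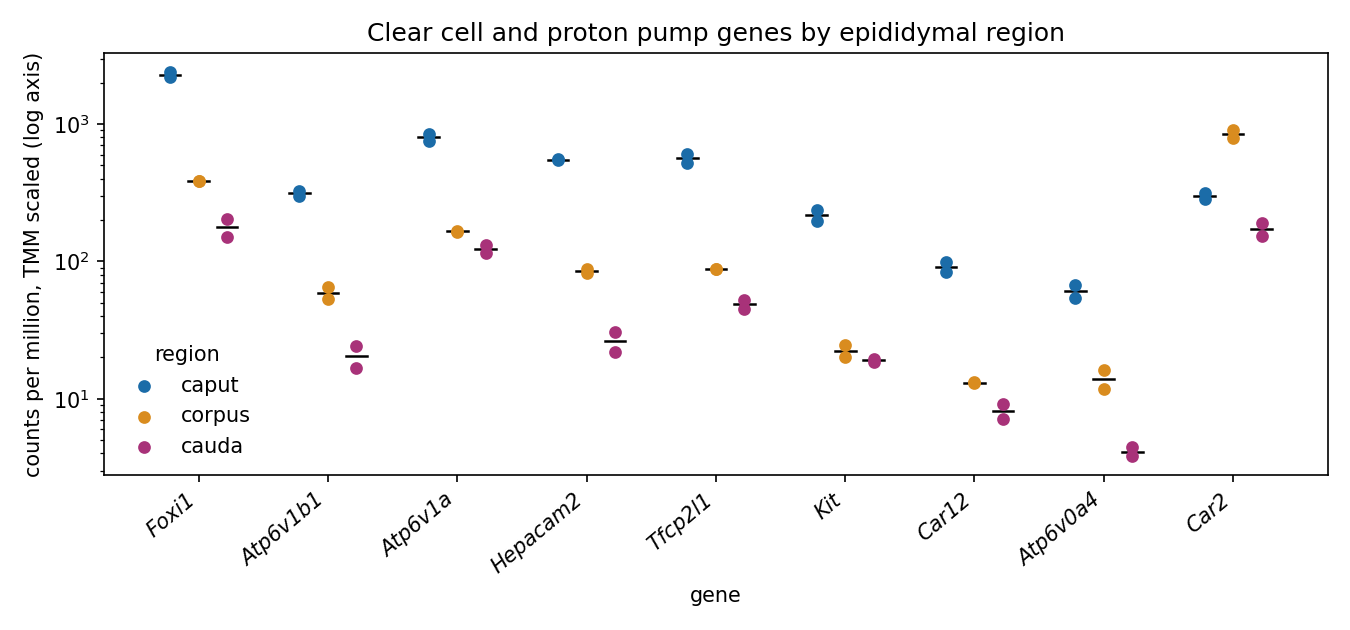
Levels of clear cell and V-ATPase genes in each library, in TMM-scaled CPM on a log axis, with a point per library (2 per region) and a bar at each region's mean. The first 8 genes are highest in caput in both libraries, Foxi1 at 2287 CPM against 177 in cauda, while Car2 is highest in corpus at 847 CPM.

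Between caput and cauda, the ends of the duct, clear cell markers were higher in caput and most ribosomal protein genes were lower there. Hepacam2, a surface protein of proton-secreting cells, fell from 551 ± 9.07 CPM in caput to 26.3 ± 5.96 in cauda (4.39 ± 0.14 log2, adjusted p = 3.90e-08). Cd52, which encodes a glycoprotein passed to maturing sperm, rose from 1592 ± 180 to 57210 ± 5400 CPM (-5.17 ± 0.13, adjusted p = 4.41e-09). The epididymal lipocalins Lcn8 and Lcn9, small ligand-binding secreted proteins, were almost confined to caput in these libraries, at 602 ± 460 and 416 ± 253 CPM against 0.589 ± 0.0924 and 0.285 ± 0.172 in cauda. In total 10581 genes differed (66.9% of those tested), 5363 higher in caput and 5218 lower, of which 6579 had an absolute log2 change of at least 1. The counts of list members called below are to be read against that share. Scaling by library totals alone shifted the median fold change by 0.86 and turned the split into 9501 higher and 2564 lower, so changes here are relative to the bulk of the genes. 

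Clear cell markers were higher in caput for 15 of 15 measured members (15 adjusted over the list alone), with a median log2 fold change of 3.51 and a camera adjusted p of 7.23e-06. The call was lost with an estimated correlation (adjusted p = 0.715 with an estimated correlation). Foxi1 was higher by 3.69 ± 0.14 (adjusted p = 9.44e-08), Atp6v1b1 by 3.94 ± 0.19 (adjusted p = 1.46e-06), the transcription factor Tfcp2l1 by 3.54 ± 0.11 and Car12, a membrane carbonic anhydrase, by 3.5 ± 0.14 (adjusted p at most 5.26e-08). Of 24 V-ATPase subunits, 16 were higher and 4 lower in caput (16 and 4 adjusted over the list alone), median 0.89, camera adjusted p = 0.0157, and adjusted p = 0.726 with an estimated correlation. Atp6v1a, the catalytic subunit, was higher by 2.69 ± 0.1 and Atp6v0b by 1.6 ± 0.08, whereas the widely expressed Atp6v1g1 was lower at -1.63 ± 0.08 (adjusted p at most 2.12e-07). Library totals gave the V-ATPase list a median of 1.75, with 22 and 2 members higher and lower. Among 28 acid-base transport genes, 18 were higher and 7 lower (18 and 7 adjusted over the list alone; camera adjusted p = 0.084). Clcn5, an endosomal chloride/proton exchanger, was higher by 3.93 ± 0.13 and the carbonic anhydrase gene Car14 lower at -6.74 ± 0.14 (adjusted p at most 1.92e-08). The clear cell list shares members with the V-ATPase list, such as Atp6v1b1 and Atp6v0a4, and with the acid-base list, such as Car2 and Car12. Their results are therefore not independent.

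Luminal secretory genes, short here for the list of principal cell and luminal secretory genes, parted into a caput set and a cauda set. Of 33 measured members, 18 were higher in caput and 15 lower (the same numbers adjusted over the list alone). Camera gave adjusted p = 0.948 in favour of caput. Under library totals it gave 0.0472 in favour of cauda relative to all other genes, while the median over all tested genes shifted by 0.86 towards caput. The 8 genes that the rule on fold change named as higher in caput were all members of this list. Lcn6 had no reads in cauda and was at least 1010-fold higher, against a floor of 3 counts over the group. Few reads in cauda left Cst8 higher 3300-fold (95% counting interval 593 to 130000), Lcn10 2050-fold (95% counting interval 566 to 16900) and Adam28 1230-fold (95% counting interval 340 to 10100). Lcn9, Cst11, Cst12 and Lcn8 were higher by 10.5 ± 0.96, 10.16 ± 0.81, 10.15 ± 1.7 and 9.98 ± 1.11 (adjusted p at most 0.0084). The Adam28 call (adjusted p = 0.0224) was lost without cauda 1 (adjusted p = 0.104) or cauda 2 (adjusted p = 0.0958) and with no filter on low counts (adjusted p = 0.0687). Caput 2 held more of these transcripts than caput 1: in caput 1 and 2, Lcn8 measured 276.85 and 926.73 CPM, Cst8 55.99 and 135.99, Lcn10 67.25 and 170.96 and Adam28 29.21 and 115.6. Without caput 2 the log2 changes of Lcn9, Cst11, Cst12 and Lcn8 became 9.69, 9.52, 8.58 and 8.86. Without caput 1 the log2 changes of Cst12 and Lcn8 became 10.89 and 10.61. Without cauda 1 the log2 change of Cst12 became 9.54. At most 3 reads stayed in the lower region for Lcn9 without cauda 1 and for Cst12 without cauda 2, too few for a fold. In the cauda set, the lipocalin Lcn12 and the WAP-domain genes Wfdc15b and Wfdc10 were lower in caput at -5.34 ± 0.09, -5.38 ± 0.11 and -4.74 ± 0.1 (adjusted p at most 1.47e-09), and Aqp9 at -3.33 ± 0.25 (adjusted p = 0.000112). Clear cell markers moved opposite to this cauda set, with a median of 3.51 in favour of caput.

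Cauda was set apart by further genes with little or no signal in caput. S100a8, a calcium-binding protein of innate immunity, had no caput reads and was at least 853-fold lower there. Lce6a, a cornified envelope gene, was lower in caput 1290-fold (95% counting interval 356 to 10700) and the lens crystallin gene Crygc 1430-fold (95% counting interval 256 to 56600). Smpx, Svs1, Slc7a15, Spink14 and Psca were lower in caput at -8.52 ± 0.13, -8.49 ± 0.76, -8.48 ± 0.39, -8.38 ± 0.7 and -8.23 ± 0.36 (adjusted p at most 0.00114). Svs1, a seminal vesicle secretory protein gene, reached 238 ± 43.3 CPM in cauda, and Spink14, a Kazal-type inhibitor gene, 2439 ± 53.4 CPM. Without caput 1 the log2 changes of Svs1 and Slc7a15 became -7.47 and -7.85. Without caput 2 the log2 changes of Slc7a15 and Psca became -9.41 and -7.47. At most 3 reads stayed in the lower region for Svs1 without caput 2 and for Psca without caput 1, too few for a fold. Clear cell markers were lower in these cauda libraries.

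Immune and defence genes moved in both directions between caput and cauda. Of 36 beta-defensins, secreted antimicrobial peptides, 15 were higher and 16 lower in caput (15 and 16 adjusted over the list alone). Their median of -0.4 turned positive, to 0.45 with 16 higher and 14 lower, under library totals and to 0.46 with 17 and 14 with the gene length trend removed. Under library totals camera called the list lower in caput relative to all other genes (adjusted p = 0.00921). The median over all tested genes shifted by 0.86 towards caput under that scaling, so this call is not a fall of the list itself. Defb9, Defb2 and Defb11 were lower in caput at -7.82 ± 0.12, -7.08 ± 0.11 and -5.47 ± 0.1 (adjusted p at most 1.17e-09). Pattern recognition and NF-kB genes were higher for 19 of 32 and lower for 6 (19 and 6 adjusted over the list alone), led by Nfkb2 at 3.63 ± 0.13 and the viral RNA sensor Ddx58 at 3.2 ± 0.16, with Irak1 lower at -2.49 ± 0.1 (adjusted p at most 1.35e-07). Interferon response genes were higher for 20 of 36 and lower for 6 (20 and 6 adjusted over the list alone), among them Ifitm2 at 2.34 ± 0.13 (adjusted p = 3.25e-07). With all libraries, TMM scaling and region as the only factor, camera did not call these 3 lists (adjusted p = 0.525, 0.0728 and 0.0588). Without caput 2 the pattern recognition list was called (0.0447), and the interferon list was called without caput 2 (0.0449), corpus 1 (0.0424), corpus 2 (0.0374) or cauda 2 (0.0202). Among 33 cytokines and chemokines, 14 were higher and 7 lower (14 and 7 adjusted over the list alone), with Tgfb3 higher by 4.95 ± 0.17, Il34 by 5.32 ± 0.2 and Cxcl16 by 2.99 ± 0.19 (adjusted p at most 6.44e-07). The antimicrobial and mucosal list had 8 of 17 higher and 5 lower (8 and 5 adjusted over the list alone), with a median of 1.04 but a mean of -0.57. The mucin gene Muc20 was higher by 3.59 ± 0.11 and Ido1, a tryptophan-degrading enzyme, lower at -3.74 ± 0.09 (adjusted p at most 1.08e-08). B2m, the light chain of MHC class I, was lower in caput at -3.01 ± 0.1 (adjusted p = 1.29e-08), in a class I list with 10 of 23 higher and 7 lower (10 and 7 adjusted over the list alone). MHC class II genes were higher for 4 of 13 and complement genes lower for 8 of 18 with 2 higher (the same numbers adjusted over the list alone). Camera gave complement genes adjusted p = 0.153, and 0.0095 under library totals. Library totals moved the medians of pattern recognition, interferon, cytokine, antimicrobial, class I, class II and complement genes from 0.9, 0.63, 0.46, 1.04, 0.28, 0.34 and -1.43 to 1.76, 1.49, 1.31, 1.9, 1.14, 1.21 and -0.58, with 24, 28, 19, 10, 16, 5 and 4 higher and 5, 2, 6, 5, 5, 0 and 6 lower. Removing the length trend moved those of cytokine, antimicrobial and class II genes to 0.73, 1.66 and 0.53, with 13, 9 and 5 higher and 8, 5 and 0 lower, and left 17 and 2 interferon genes higher and lower. Clear cell markers were higher in caput throughout.

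Most ribosomal protein, oxidative phosphorylation and antioxidant genes were lower in caput under TMM scaling, the last with a median of 0.08 under library totals. Of 82 ribosomal protein genes, 73 were lower and 0 higher (76 lower adjusted over the list alone), median -1.99, camera adjusted p = 2.44e-16; Rpl41 and Rpl32 were lower at -2.72 ± 0.08 and -2.61 ± 0.08. Of 76 oxidative phosphorylation genes, 58 were lower and 9 higher (59 and 9 adjusted over the list alone), median -1.06, camera adjusted p = 2.54e-08, with Ndufa1 of complex I at -3.15 ± 0.08 and Cox4i1 of complex IV at -2.48 ± 0.08. Antioxidant genes were lower for 30 of 47 and higher for 9 (30 and 9 adjusted over the list alone), median -0.78, camera adjusted p = 0.00324, and Gpx3, the secreted glutathione peroxidase, was lower at -4.08 ± 0.11. The named members had adjusted p of at most 1.58e-08. All 3 list calls were lost with an estimated correlation (adjusted p = 0.715 with an estimated correlation), and under library totals the medians became -1.12 for ribosomal proteins, -0.2 for oxidative phosphorylation and 0.08 for antioxidant genes. The counts were then 5, 25 and 20 higher and 57, 37 and 20 lower. Short genes as a class were lower in caput, with a median of -1.08 in the shortest of 8 length classes and 0.41 in the longest. Removing that length trend left medians of -1.3 for ribosomal proteins and -0.41 for oxidative phosphorylation, with 0 and 16 higher and 60 and 47 lower.

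Basal cell markers were higher in caput for 13 of 16 members and lower for 0 (13 and 0 adjusted over the list alone), median 1.45, camera adjusted p = 0.00324 and adjusted p = 0.715 with an estimated correlation. Under library totals the median was 2.31 with 14 higher and 0 lower, and camera, which compares a list with all other genes, no longer called it (adjusted p = 0.0551). The adhesion genes Dst, Itgb4 and Itga3 were higher by 2.69 ± 0.11, 2.94 ± 0.21 and 1.53 ± 0.11, and Krt5 by 2.29 ± 0.43 (adjusted p at most 0.00645). Immediate early and dissociation genes, which respond within minutes to handling, were higher in caput for 29 of 35 and lower for 1 (29 and 2 adjusted over the list alone), median 1.5, camera adjusted p = 7.86e-06 and adjusted p = 0.715 with an estimated correlation. Hspa1b was higher by 2.03 ± 0.1 and Btg2 by 2.1 ± 0.1 (adjusted p at most 1.65e-07). Library totals gave the immediate early list a median of 2.36. Markers of other cells changed in fewer members. Mononuclear phagocyte markers were higher for 3 of 19 and lower for 2 (1 and 2 adjusted over the list alone). The latter were Cd52, which epididymal epithelium also expresses, and Itgam, at 0.718 ± 0.144 CPM in caput and 12.58 ± 1.13 in cauda. Lymphocyte markers were higher for 2 of 9 and lower for 1 (1 and 0 adjusted over the list alone). Stromal markers were lower for 6 of 17 and higher for 3 (6 and 3 adjusted over the list alone). Their median of -0.66 became 0.2 under library totals, with 5 higher and 3 lower. Sperm transcripts were higher for 4 of 15 (1 adjusted over the list alone), and camera called that list only without caput 1 (adjusted p = 0.00542, against 0.51 with all libraries). Library totals moved the medians of phagocyte, lymphocyte and sperm markers from 0.3, 0.07 and 0.4 to 1.16, 0.93 and 1.26, with 6, 2 and 5 higher and 2, 1 and 0 lower, and removing the length trend moved those of phagocyte and lymphocyte markers to 0.88 and 0.37. Prm1, with 2 reads in the cauda libraries together, was higher in caput (adjusted p = 0.0194), a call lost without cauda 1 (adjusted p = 0.0897) or cauda 2 (adjusted p = 0.0789) and with only the 4 libraries compared (adjusted p = 0.0771). It measured 7.16 and 46.07 CPM in caput 1 and 2. Ptprc was higher by 1.42 ± 0.55 (adjusted p = 0.0464), and the call was lost when any library but caput 1 or cauda 2 was left out, with adjusted p between 0.0677 and 0.237, with only the 4 libraries compared (0.0641), with the length trend removed (0.143) and in limma on log2(RPKM + 1) without a minimum (0.122). Without cauda 2 the log2 change of Ptprc became 2.38. The only red blood cell gene measured, Alas2, gave -0.22 ± 0.2 (adjusted p = 0.351), and 0.64 (adjusted p = 0.0173) under library totals.

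Several smaller lists divided between caput and cauda without a camera call, in a comparison where 66.9% of all tested genes were called. Hox genes, which pattern the body axis, were lower in caput for 12 of 27 and higher for 4 (12 and 4 adjusted over the list alone), with Hoxb7 lower at -1.3 ± 0.07 and Hoxd3 higher by 1.49 ± 0.12. The Hox median of -0.58 became 0.29 under library totals, with 8 higher and 3 lower. Steroid and hormone receptor genes were higher for 12 of 24 and lower for 6 (12 and 7 adjusted over the list alone), including the estrogen receptor Esr1 at 2.6 ± 0.12, the retinoic acid receptor Rarb at 3.49 ± 0.16 and Hsd11b1, which regenerates active glucocorticoid, at -6.78 ± 0.18. Purinergic genes were higher for 13 of 25 and lower for 8 (13 and 9 adjusted over the list alone), with the ectonucleotidase Entpd1 at 3.69 ± 0.14 and the ATP-gated channel P2rx1 at -7.2 ± 0.31. Endocytosis and lysosome genes were higher for 25 of 44 and lower for 11 (26 and 11 adjusted over the list alone), with the lysosomal enzyme Hexa at 3.02 ± 0.1 and the endocytic receptor Lrp2 at -4.14 ± 0.11. Microvilli and actin genes were higher for 17 of 34 and lower for 11, and claudins higher for 9 of 14 and lower for 4 (the same numbers adjusted over each list alone), with Eps8 at 2.51 ± 0.1, Vill at 4.52 ± 0.18, Cldn6 at 5.88 ± 0.19 and Cldn3 at -2.14 ± 0.1. Sperm-interacting proteins were lower for 15 of 31 and higher for 12 (15 and 12 adjusted over the list alone), among them Ptgds, a prostaglandin synthase of seminal fluid, at -5.98 ± 0.13 and Spinkl at -5.53 ± 0.11. That list's median of -0.23 became 0.44 under library totals, with 15 higher and 12 lower. Cell cycle genes were higher for 5 of 30 and lower for 6 (2 and 4 adjusted over the list alone), with a median of 0.24 and a mean of -0.01. Under library totals 17 of them were higher and 3 lower, with a median of 1.09, and with the length trend removed 4 were higher and 9 lower. The medians of hormone receptor, purinergic, endocytosis, microvilli and claudin genes moved from 0.4, 0.73, 0.34, 0.33 and 0.75 to 1.26, 1.59, 1.2, 1.19 and 1.61 under library totals, with 16, 17, 33, 26 and 10 higher and 3, 8, 6, 6 and 4 lower. Those of hormone receptor, endocytosis and sperm-interacting genes moved to 0.23, 0.11 and -0.35 with the length trend removed, with 11, 19 and 12 higher and 8, 14 and 15 lower. The genes named here had adjusted p of at most 3.26e-06.

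**Figure D2:**
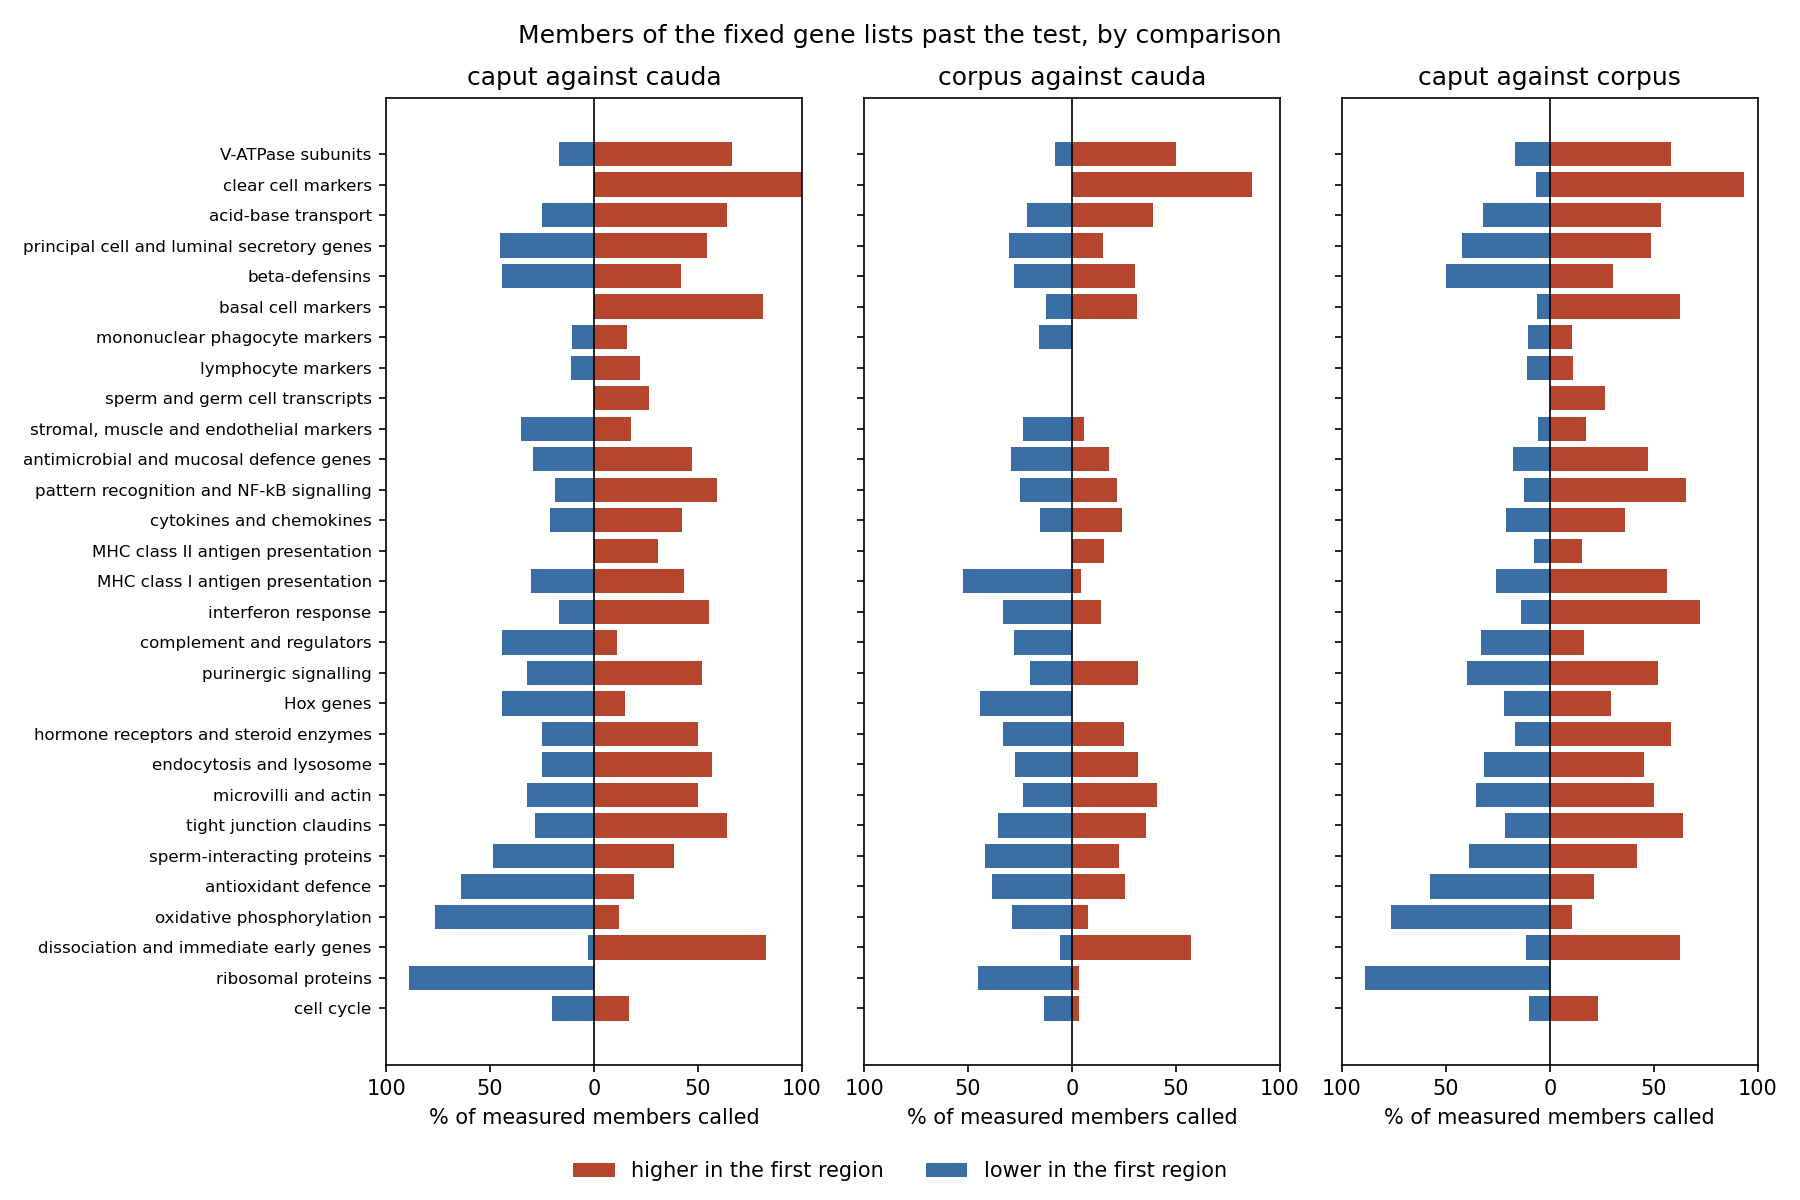
Share of each fixed list's measured members past edgeR's test, in percent, drawn to the right (red) for members higher in the first region named and to the left (blue) for members lower in it, for the 3 comparisons. Clear cell markers reach 15 of 15 higher in caput against cauda, ribosomal proteins 73 of 82 lower.

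Corpus and cauda, the neighbouring distal regions, differed in fewer genes than either did from caput. Foxi1 was higher in corpus by 1.12 ± 0.13 (adjusted p = 0.000268) and Atp6v1b1 by 1.54 ± 0.18 (adjusted p = 0.000599). Car2, a cytosolic carbonic anhydrase, was higher in corpus by 2.29 ± 0.12 (adjusted p = 2.26e-06), at 847 ± 78.6 against 173 ± 26.5 CPM. Rnase9, a secreted protein of the duct, was higher in corpus by 2.01 ± 0.1, and Cd52 was lower at -1.09 ± 0.11 (adjusted p at most 6.46e-05). Altogether 5592 genes differed (35.4% of those tested), 2742 higher in corpus and 2850 lower, of which 2602 reached a log2 change of 1. With library totals alone the median shifted by 0.27 and the split became 5154 and 1735. Aqp9 gave -0.31 ± 0.23 (adjusted p = 0.365), Krt5 -0.15 ± 0.46 (adjusted p = 0.84) and Ptprc 0.96 ± 0.56 (adjusted p = 0.224), none past the threshold. Aqp9 passed it without caput 1 (adjusted p = 0.0102) or caput 2 (adjusted p = 0.00982) and with only the 4 libraries compared (adjusted p = 0.0118). Prm1 had too few reads in both regions for a fold (adjusted p = 0.917).

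The genes most increased in corpus over cauda included Lcn5, the retinoic acid-binding lipocalin, by 8.14 ± 0.95, the beta-defensin Defb23 by 6.69 ± 0.32, the zinc transporter Slc39a8 by 6.18 ± 0.18, Sult1d1 by 6.25 ± 0.43, Dgkk by 6.15 ± 0.39 and Crhbp by 5.87 ± 0.52 (adjusted p at most 0.00606). Olfr56, an olfactory receptor gene, was higher 179-fold (95% counting interval 49.1 to 1480). Spint4 was higher by 6.33 ± 1.01 (adjusted p = 0.0148), a call lost without corpus 1 (adjusted p = 0.0561), cauda 1 (0.0819) or cauda 2 (0.0757). Crygc and the mucin gene Muc3 had no corpus reads and were at least 283-fold and at least 130-fold lower there than in cauda. Muc3 differed between the cauda libraries, at 6.63 CPM in cauda 1 and 13.9 in cauda 2. S100a8 was lower in corpus 1520-fold (95% counting interval 272 to 60000). Spink14, Smpx, Krt32, Cryba4 and Treh were lower at -9.9 ± 0.78, -9.63 ± 0.15, -8.62 ± 0.31, -8.6 ± 0.97 and -8.58 ± 0.78 (adjusted p at most 0.00544). Without corpus 2 the log2 changes of Lcn5, Spink14 and Cryba4 became 7.46, -12.39 and -11.63. Without cauda 2 the log2 change of Lcn5 became 7.11. Without corpus 1 the log2 changes of Spink14, Cryba4 and Treh became -9.06, -7.73 and -7.67. At most 3 reads stayed in the lower region for Lcn5, Sult1d1 and Dgkk without cauda 1 and for Treh without corpus 2, too few for a fold.

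Clear cell markers were higher in corpus than cauda for 13 of 15 and lower for 0 (13 and 0 adjusted over the list alone), median 1.12, camera adjusted p = 5.15e-05 and adjusted p = 0.715 with an estimated correlation. V-ATPase subunits were higher for 12 of 24 and lower for 2 (13 and 2 adjusted over the list alone; camera adjusted p = 0.0678, and 0.0351 without corpus 1, 0.033 without cauda 2 or 0.0335 under library totals), with Atp6v0a4 at 1.77 ± 0.2 and Atp6v0e2 at -0.64 ± 0.09. Acid-base transport genes were higher for 11 of 28 and lower for 6 (11 and 6 adjusted over the list alone), Car14 being lower at -5.71 ± 0.14 and the anion exchanger Slc26a7 at -3.44 ± 0.28. Luminal secretory genes were higher for 5 of 33 and lower for 10 (5 and 11 adjusted over the list alone; camera adjusted p = 0.365, and 0.0265 under library totals), Lcn12 at -2.3 ± 0.07 and Wfdc15b at -1.42 ± 0.09, beside the higher clear cell markers of corpus. Beta-defensins were higher for 11 of 36 and lower for 10 (12 and 10 adjusted over the list alone), Defb29 at 4.99 ± 0.19 and Defb2 at -3.05 ± 0.09. Adjusted p of the named genes was at most 0.000532. Library totals moved the medians of the V-ATPase, acid-base, luminal and beta-defensin lists from 0.28, 0.21, -0.31 and 0.1 to 0.55, 0.46, -0.04 and 0.37, with 16, 12, 6 and 14 higher and 1, 6, 9 and 10 lower.

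MHC class I antigen presentation genes were lower in corpus than in cauda for 12 of 23 and higher for 1 (13 and 2 adjusted over the list alone), median -0.44, camera adjusted p = 0.0088; B2m was lower at -1.08 ± 0.09, the immunoproteasome subunit Psmb8 at -1.66 ± 0.13 and the lipid-presenting Cd1d1 at -4.41 ± 0.38. Hox genes were lower for 12 of 27 and higher for 0 (12 and 0 adjusted over the list alone), median -0.53, camera adjusted p = 0.00229, with Hoxb9 at -2.14 ± 0.11 and Hoxa10 at -2.59 ± 0.32. Interferon response genes were lower for 12 of 36 and higher for 5 (14 and 5 adjusted over the list alone), camera adjusted p = 0.0468, a call lost without corpus 1 (adjusted p = 0.0846) or cauda 2 (adjusted p = 0.239), with a prior count of 0.5 (adjusted p = 0.0564) and with the gene length trend removed (adjusted p = 0.0567). Irf1 and Igtp were lower at -1 ± 0.12 and -1.46 ± 0.18, and Irf9 was higher by 1.05 ± 0.08. Ribosomal protein genes were lower for 37 of 82 and higher for 3 (39 and 4 adjusted over the list alone), median -0.33, camera adjusted p = 0.000194, Rplp1 at -0.84 ± 0.08 and Rpl3l, a muscle-type paralog, at 1.55 ± 0.1. Immediate early genes were higher for 20 of 35 and lower for 2 (21 and 2 adjusted over the list alone), median 0.73, camera adjusted p = 8.89e-05, with Hspa1b at 1.57 ± 0.09 and Dnajb1 at 1.59 ± 0.1. Library totals moved the medians of class I, Hox, interferon and ribosomal protein genes from -0.44, -0.53, -0.48 and -0.33 to -0.17, -0.25, -0.22 and -0.06, with 4, 1, 5 and 9 higher and 9, 9, 9 and 16 lower. Without corpus 2 the log2 change of Cd1d1 became -5.24. These 5 list calls were lost with an estimated correlation (adjusted p = 0.715 with an estimated correlation). The genes named had adjusted p of at most 0.000326, and 13 of 15 clear cell markers were higher in corpus over the same comparison.

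The other lists had no camera call between corpus and cauda with all libraries and TMM scaling. Antioxidant genes were higher for 12 of 47 and lower for 18 (13 and 20 adjusted over the list alone), with the glutathione transferase Gstm6 at 2.31 ± 0.08 and Gpx6 at -6.46 ± 0.29. Oxidative phosphorylation genes were higher for 6 of 76 and lower for 22 (7 and 27 adjusted over the list alone). Their median of -0.12 became 0.15 under library totals, with 27 higher and 3 lower, against 9 higher and 18 lower with the length trend removed. Camera called them without corpus 2 (adjusted p = 0.0278) or cauda 2 (0.0317). Endocytosis and lysosome genes were higher for 14 of 44 and lower for 12 (14 and 12 adjusted over the list alone), Hexa at 2.16 ± 0.1 and Lrpap1, the chaperone of LDL-receptor-family proteins, at -2.75 ± 0.09. Sperm-interacting proteins were higher for 7 of 31 and lower for 13 (8 and 13 adjusted over the list alone; camera adjusted p = 0.0278 without corpus 2 and 0.0263 under library totals), with the sterol-binding Npc2 at 2.16 ± 0.1 and Ggt1 at -3.55 ± 0.18. Steroid and hormone receptor genes were higher for 6 of 24 and lower for 8 (6 and 9 adjusted over the list alone), with the testosterone-converting Srd5a1 at 2.51 ± 0.1 and the retinoic acid receptor Rara at -2.83 ± 0.16. Purinergic genes were higher for 8 of 25 and lower for 5 (8 and 5 adjusted over the list alone), with Enpp2 at 3.74 ± 0.1 and P2rx1 at -5.32 ± 0.28. Complement genes were lower for 5 of 18 and higher for 0 (5 and 0 adjusted over the list alone), including clusterin, Clu, at -3.04 ± 0.29. Camera called the list without caput 1 (adjusted p = 0.0334), caput 2 (0.0346) or cauda 2 (0.0382) and under library totals (0.0082). Adjusted p of the genes named so far was at most 0.00111. Cytokine genes were higher for 8 of 33 and lower for 5, pattern recognition genes higher for 7 of 32 and lower for 8, antimicrobial genes higher for 3 of 17 and lower for 5, microvilli genes higher for 14 of 34 and lower for 8, claudins 5 and 5 of 14, and cell cycle genes 1 and 4 of 30. Adjusted over the list alone these were 8 and 6, 7 and 8, 5 and 6, 15 and 9, 6 and 5, and 1 and 3. Medians of the antioxidant, hormone receptor, pattern recognition and cell cycle lists turned from -0.01, -0.17, -0.09 and -0.14 to 0.25, 0.11, 0.17 and 0.12 under library totals, with 20, 9, 8 and 2 members higher and 13, 7, 6 and 2 lower. Antimicrobial genes then had 5 higher and 5 lower, and claudins 7 and 4. Cytokine genes had a median of 0.08 and a mean of -0.13, claudins 0.12 and -0.05. Basal markers were higher for 5 of 16 and lower for 2 (5 and 2 adjusted over the list alone), with a median of -0.07, a mean of 0.13 and, under library totals, a median of 0.21 with 5 higher and 1 lower. Phagocyte markers were lower for 3 of 19 (2 adjusted over the list alone; 2 higher and 2 lower under library totals, with camera adjusted p = 0.0472). Stromal markers were lower for 4 of 17 and higher for 1 (4 and 1 adjusted over the list alone; camera adjusted p = 0.0204 without caput 1, 0.0195 without caput 2 and 0.00877 under library totals), and MHC class II genes higher for 2 of 13 (1 adjusted over the list alone). Lymphocyte and sperm markers had 0 calls by edgeR in either direction over all genes or the list alone, with 1 of 9 and 1 of 15 at an unadjusted p under 0.05. Under library totals 1 lymphocyte marker was higher. The medians of endocytosis, sperm-interacting, purinergic, complement, cytokine, microvilli and class II genes moved from 0, -0.31, 0.27, -0.51, 0.08, 0.23 and 0.37 to 0.27, -0.05, 0.54, -0.24, 0.35, 0.49 and 0.63 under library totals, with 21, 8, 12, 0, 8, 18 and 3 higher and 7, 11, 4, 4, 6, 5 and 0 lower, and those of phagocyte, antimicrobial and claudin genes from -0.32, -0.53 and 0.12 to -0.07, -0.26 and 0.39. The endocytosis median was -0.03 with the length trend removed. The heme synthesis gene Alas2 was higher in corpus by 3.28 ± 0.19 (adjusted p = 2.09e-06).

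Caput and corpus, the neighbouring proximal regions, differed about as widely as caput and cauda. Foxi1 was higher in caput by 2.57 ± 0.14 (adjusted p = 7.10e-07), Atp6v1b1 by 2.4 ± 0.17 (adjusted p = 1.51e-05) and Krt5 by 2.44 ± 0.44 (adjusted p = 0.00546). Npy, the neuropeptide Y gene, was lower in caput at -4.51 ± 0.15 (adjusted p = 5.91e-08), at 210 ± 37.3 against 4769 ± 191 CPM. Gpx5, the secreted epididymal glutathione peroxidase, was higher in caput by 10.05 ± 0.47 (adjusted p = 4.59e-05), at 1839 ± 666 against 1.7 ± 0.821 CPM, and stood at 606 ± 2.86 CPM in cauda. Without corpus 2 the log2 change of Gpx5 became 10.67. Aqp9 was lower in caput at -3.02 ± 0.25 (adjusted p = 0.00018), and Ptprc gave 0.45 ± 0.52 (adjusted p = 0.464). In all, 10275 genes differed (65% of those tested), 5246 higher in caput and 5029 lower, of which 6181 reached a log2 change of 1. Library totals alone shifted the median by 0.59 and gave 8438 higher and 2972 lower.

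**Figure D3:**
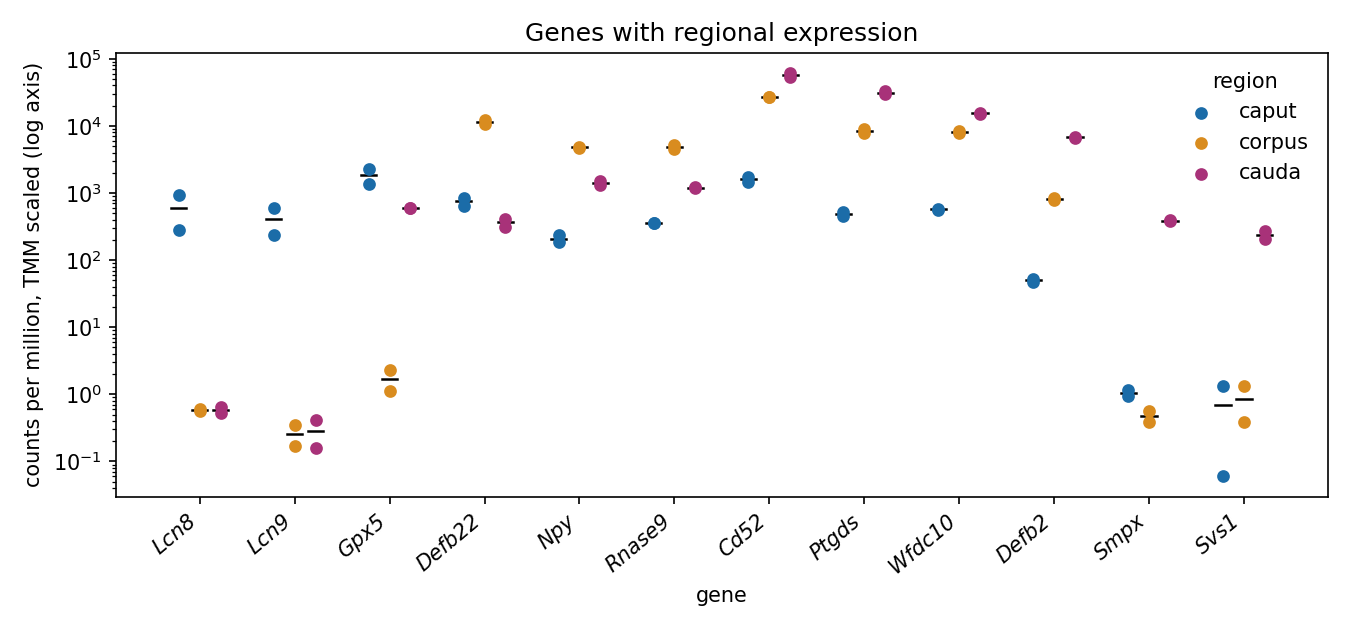
Levels of 12 genes with regional expression in each library, in TMM-scaled CPM on a log axis, with a point per library (2 per region) and a bar at each region's mean. Lcn8 and Lcn9 are high in caput, Defb22, Npy and Rnase9 in corpus, and Cd52 to Svs1 in cauda; Gpx5 is lowest in corpus at 1.7 CPM.

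The 8 genes named by fold change as higher in caput than corpus included members of the luminal list and of the sperm list. Adam28 had no corpus reads and was at least 866-fold higher (adjusted p = 0.0221), a call lost without cauda 1 (adjusted p = 0.0539), with no filter on low counts (adjusted p = 0.0676) and with only the 4 libraries compared (adjusted p = 0.101). Cst8 was higher 1750-fold (95% counting interval 483 to 14400). Lcn9, Lcn8 and the ribonuclease gene Rnase10 were higher by 10.58 ± 0.96, 9.99 ± 1.11 and 9.83 ± 1.29 (adjusted p at most 0.00415). Cst12 was higher by 10.23 ± 1.69 (adjusted p = 0.00855), a call lost without corpus 1 (adjusted p = 0.0572) or corpus 2 (adjusted p = 0.0567). The sperm chromatin gene Prm2 was higher 1110-fold (95% counting interval 199 to 44000) and Prm1 by 7.89 ± 1.75 (adjusted p = 0.0266 and 0.0206). Without corpus 1 these became 0.124 and 0.106, without corpus 2 0.124 and 0.103, with no filter on low counts 0.0637 and 0.0505, and with only the 4 libraries compared 0.0653 and 0.0551. In caput 1 and 2, Prm2 measured 7.13 and 55.77 CPM, Prm1 7.16 and 46.07, Adam28 29.21 and 115.6 and Cst8 55.99 and 135.99. Without caput 2 the log2 changes of Lcn9, Lcn8, Rnase10, Cst12 and Prm1 became 9.77, 8.87, 8.94, 8.66 and 6.0. Without caput 1 the log2 changes of Lcn8, Cst12 and Prm1 became 10.62, 10.96 and 8.68. Without corpus 1 the log2 change of Cst12 became 9.63. At most 3 reads stayed in the lower region for Lcn9, Cst12 and Prm1 without corpus 2, too few for a fold. Higher in corpus were the metalloprotease gene Mep1a, Defb9, the casein gene Csn1s2a, Npy, the transcription factor Gfi1b, Cd177, Dapl1 and Defb40. Their log2 fold changes lay between -5.21 for Mep1a and -4.43 for Defb40, with adjusted p of at most 2.49e-06.

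Clear cell markers were higher in caput than corpus for 14 of 15 (14 adjusted over the list alone), median 2.41, camera adjusted p = 0.000348 and adjusted p = 0.715 with an estimated correlation. The exception, Car2, was lower in caput, at 299 ± 20.1 against 847 ± 78.6 CPM. Kit, a receptor tyrosine kinase, was higher by 3.28 ± 0.14 and Tfcp2l1 by 2.68 ± 0.11. V-ATPase subunits were higher for 14 of 24 and lower for 4 (14 and 4 adjusted over the list alone), camera adjusted p = 0.0322, adjusted p = 0.743 with an estimated correlation and 0.0525 without corpus 1. Atp6v1a was higher by 2.27 ± 0.1 and Atp6v1g1 lower at -1.9 ± 0.08. Acid-base transport genes were higher for 15 of 28 and lower for 9 (17 and 9 adjusted over the list alone), including the anion exchanger Slc26a3 at 2.9 ± 0.1 and Clcn5 at 2.78 ± 0.12. Luminal secretory genes were higher for 16 of 33 and lower for 14 (16 and 14 adjusted over the list alone), with Wfdc15b at -3.96 ± 0.1 and Lcn12 at -3.04 ± 0.08. Beta-defensins were higher for 11 of 36 and lower for 18 (11 and 18 adjusted over the list alone; camera adjusted p = 0.0728, and 0.00145 under library totals), with Defb43 at -4.25 ± 0.09. Adjusted p of these genes was at most 1.27e-07. Library totals moved the medians of the V-ATPase, acid-base and beta-defensin lists from 0.63, 0.97 and -1.26 to 1.22, 1.55 and -0.67, with 21, 18 and 11 higher and 3, 7 and 16 lower, and removing the length trend left beta-defensins at -0.55.

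Interferon response genes were higher in caput than corpus for 26 of 36 and lower for 5 (26 and 6 adjusted over the list alone), median 1.56, camera adjusted p = 0.00324, with Oasl2 at 3.39 ± 0.27 and Ifitm2 at 1.92 ± 0.13, while Irf9 was at -1.05 ± 0.08. Pattern recognition and NF-kB genes were higher for 21 of 32 and lower for 4 (21 and 5 adjusted over the list alone), median 1.03, camera adjusted p = 0.0131, and 0.0517 without corpus 2 or 0.0571 under library totals, where the median was 1.62 with 25 higher and 2 lower. Nfkb2 was higher by 2.67 ± 0.12 and Tnfaip3, which restrains NF-kB signalling, by 2.57 ± 0.16. Basal markers were higher for 10 of 16 and lower for 1 (10 and 1 adjusted over the list alone), median 1.71, camera adjusted p = 0.0242, and 0.1 under library totals, where the median was 2.3 with 13 higher and 1 lower. Itgb4 was higher by 2.63 ± 0.2. Immediate early genes were higher for 22 of 35 and lower for 4 (23 and 4 adjusted over the list alone), median 0.47, camera adjusted p = 0.0158, with Klf4 at 2.67 ± 0.24. These 4 list calls were lost with an estimated correlation (adjusted p = 0.715 with an estimated correlation). Class I genes were higher for 13 of 23 and lower for 6 (13 and 6 adjusted over the list alone; camera adjusted p = 0.232), Psmb8 at 2.19 ± 0.13 and B2m at -1.93 ± 0.09. Cytokine genes were higher for 12 of 33 and lower for 7 (12 and 7 adjusted over the list alone), among them Cxcl16 at 3.93 ± 0.2 and Tgfb3 at 3.35 ± 0.14. The medians of immediate early, class I and cytokine genes moved from 0.47, 1.04 and 0.85 to 1.06, 1.63 and 1.41 under library totals, with 27, 16 and 15 higher and 1, 4 and 4 lower. Interferon genes then had 27 higher and 1 lower. Adjusted p of the genes named was at most 1.36e-05, and 14 of 15 clear cell markers were higher in caput over the same comparison.

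Ribosomal protein genes were lower in caput than corpus for 73 of 82 and higher for 0 (76 and 0 adjusted over the list alone), median -1.59, camera adjusted p = 4.84e-17. Oxidative phosphorylation genes were lower for 58 of 76 and higher for 8 (58 and 8 adjusted over the list alone), median -0.99, camera adjusted p = 3.52e-08. Antioxidant genes were lower for 27 of 47 and higher for 10 (27 and 10 adjusted over the list alone), median -0.94, camera adjusted p = 0.0088, and 0.0687 with the gene length trend removed. With an estimated correlation the adjusted p was 0.715 for each of the 3. Library totals left the 3 medians at -1, -0.4 and -0.35, with 2, 19 and 16 higher and 58, 44 and 23 lower. Rps26 was lower at -2.87 ± 0.08, Ndufb7 at -2.59 ± 0.08, Gstm6 at -2.79 ± 0.08 and Gpx3 at -3.36 ± 0.1 (adjusted p at most 2.68e-08). The length trend was present here too, at -1.01 in the shortest of 8 length classes and 0.35 in the longest, and its removal left medians of -0.97 for ribosomal proteins and -0.35 for oxidative phosphorylation, with 1 and 16 higher and 60 and 47 lower. In the remaining lists, Hox genes were higher for 8 of 27 and lower for 6 (8 and 6 adjusted over the list alone), with a median of -0.12, a mean of 0.49 and medians of 0.46 under library totals, where 12 were higher and 1 lower, and 0.03 with the length trend removed. Hoxb9 was higher by 2.31 ± 0.11. Steroid and hormone receptor genes were higher for 14 of 24 and lower for 4 (14 and 4 adjusted over the list alone), Rarb at 3.07 ± 0.15 and Srd5a1 at -2.21 ± 0.1. Endocytosis and lysosome genes were higher for 20 of 44 and lower for 14 (20 and 14 adjusted over the list alone), Npc2 at -3.44 ± 0.11, with a median of 0.2 and a mean of -0.01. Purinergic genes were higher for 13 of 25 and lower for 10, microvilli genes higher for 17 of 34 and lower for 12, claudins 9 and 3 of 14, sperm-interacting proteins 13 and 12 of 31 (median 0.43, mean -0.55), and antimicrobial genes 8 and 3 of 17, each the same adjusted over the list alone. Entpd1 was higher by 2.65 ± 0.13, Gsn by 2.81 ± 0.13, Cldn4 by 3.23 ± 0.12 and Muc20 by 2.7 ± 0.1, and Spinkl was lower at -4.03 ± 0.1. Complement genes were higher for 3 of 18 and lower for 6 (3 and 4 adjusted over the list alone), their median of -0.46 becoming 0.12 under library totals, with 5 higher and 1 lower. Cell cycle genes were higher for 7 of 30 and lower for 3 (4 and 3 adjusted over the list alone), and 13 and 2 under library totals. Removing the length trend left cell cycle genes at 5 and 5 and sperm-interacting proteins at 11 and 12. Phagocyte markers were 2 higher and 2 lower of 19 (1 and 1 adjusted over the list alone; 7 and 1 under library totals, 6 and 2 with the length trend removed), lymphocyte markers 1 and 1 of 9 (2 and 0, and 2 and 1, in the same settings). Stromal markers were 3 and 1 of 17 (3 and 0 adjusted over the list alone), MHC class II genes 2 and 1 of 13, and sperm transcripts 4 and 0 of 15 (0 and 0 adjusted over the list alone, 4 at an unadjusted p under 0.05). Camera called the sperm list without caput 1 (adjusted p = 0.000538) or corpus 2 (0.019). The medians of hormone receptor, endocytosis, purinergic, microvilli, claudin, sperm-interacting and antimicrobial genes moved from 1.05, 0.2, 0.61, 0.18, 0.58, 0.43 and 0.94 to 1.65, 0.79, 1.2, 0.77, 1.17, 1.02 and 1.53 under library totals, with 17, 30, 14, 21, 11, 17 and 10 higher and 4, 8, 8, 8, 3, 10 and 3 lower. Those of cell cycle, phagocyte, lymphocyte, stromal, class II and sperm genes moved from 0.35, 0.62, -1.17, 0.46, 0.06 and 0.68 to 0.94, 1.22, -0.57, 1.06, 0.66 and 1.3, the last 3 with 6, 5 and 5 higher and 0, 1 and 0 lower. With the length trend removed, hormone receptor, purinergic, microvilli, sperm-interacting and antimicrobial genes had medians of 0.69, 0.32, 0.07, 0.23 and 1.64, and cell cycle, stromal, class II and sperm genes 0.06, 0.13, 0.37 and 1.26. Hormone receptor and class II genes then had 13 and 5 higher and 7 and 0 lower. Adjusted p of the genes named after the length trend was at most 2.45e-07.

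**Figure D4:**
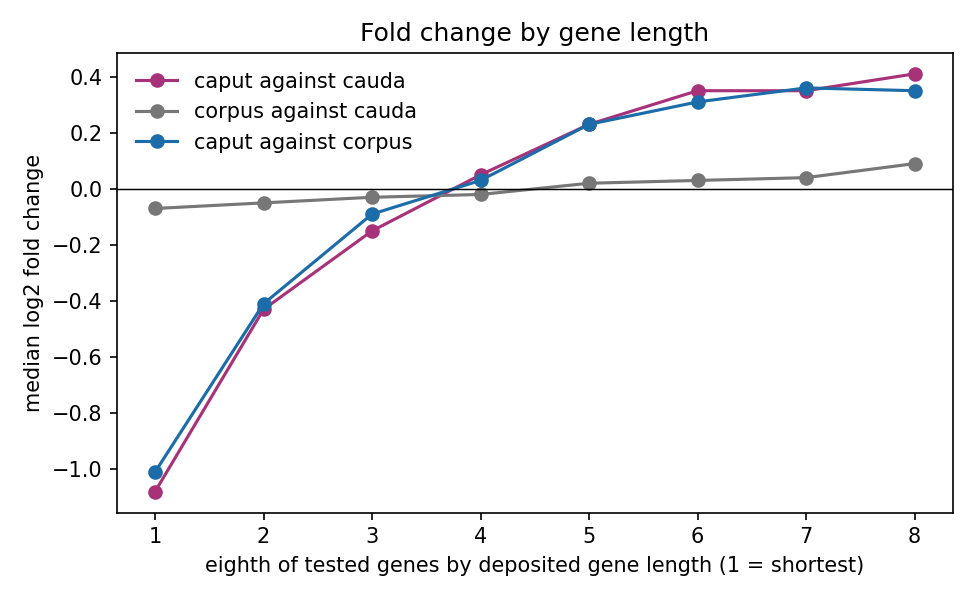
Median log2 fold change of tested genes in 8 equal classes of deposited gene length, from the shortest (1) to the longest (8), for the 3 comparisons. Both comparisons with caput rise from about -1 in the shortest class (-1.08 against cauda, -1.01 against corpus), while corpus against cauda stays between -0.07 and 0.09.

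Each region had genes above both others. Caput held 4242 such genes, led by Lcn9, Cst8, Adam28, Cst12 and Lcn8, of which Adam28 lost a call without cauda 1 (adjusted p = 0.104 and 0.0539) or cauda 2 (0.0958) and Cst12 without corpus 1 (0.0572) or corpus 2 (0.0567). Corpus held 1353, led by BC048679, Mageb7-ps, Higd1b, the beta-defensin Defb22 and RP23-138I21.1. Defb22 reached 11420 ± 1010 CPM in corpus, against 751 ± 143 in caput and 366 ± 70.8 in cauda. BC048679 reached 1933 ± 45.1 CPM in corpus, and was lower in caput at -4.16 ± 0.41 on the scale of caput over corpus (adjusted p = 0.0014). Cauda held 1985, led by S100a8, Crygc, Smpx, Spink14 and Treh, the trehalase gene, the last at 53 ± 4.49 CPM in cauda and 0.205 ± 0.29 in caput. With library totals alone the caput count rose to 7749 and the cauda count fell to 946, and without corpus 1 the cauda count was 1323. Both tests behind each count share that region's libraries. In 20 simulated draws with no effect at most 1, 4 and 1 genes were highest in caput, corpus and cauda, and independent lists with the observed calls would share 1779, 872 and 940; part of the excess can come from the shared libraries.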

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

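Library totals as the only scaling and removal of the gene length trend were chosen after seeing the data; the other alternatives were fixed before. Of 317 calls of named genes, 291 held under every alternative run, and none reversed. Most of these genes were picked for a small adjusted p or a large fold change, so this share does not carry over to all calls. Of all 5592 genes called for corpus against cauda, 5148 were also called by the DESeq2 test. Library totals kept 4476 of them, and limma on log2(RPKM + 1) without a minimum kept 4182. Requiring a log2 change of at least 1 left 6579 genes for caput against cauda, 2602 for corpus against cauda and 6181 for caput against corpus, and 2331, 698 and 826 genes highest in caput, corpus and cauda, because that condition removes genes. With library totals alone, 7749 genes were highest in caput and 946 in cauda, since this scaling shifts the median fold change by 0.86 between caput and cauda. Leaving out each library in turn gave 1323 to 2094 genes highest in cauda, the lowest without corpus 1; a region then rests on 1 library, which is assumed to vary like the others. The call of each list was lost with an estimated correlation (0 of 87 tests called by camera, 4 at an unadjusted p under 0.05). That setting is limited to the 3 residual degrees of freedom, so it cannot tell whether correlation among genes undoes a call. For caput against cauda, the immediate early list had an estimated correlation of 0.023, near the preset 0.01. Its camera adjusted p still went from 7.86e-06 to 0.715. The replicate numbers 1 and 2 recur in each region, and the labels do not say that they pair the libraries. As a hint from the data, replicate deviations correlated at 0.187, 0.162 and 0.134 between regions, and a component with 4% of the variance was negative for each library numbered 1 and positive for each numbered 2. With the replicate number as a block, 10850, 6090, 10633 and 12187 genes were called for caput against cauda, corpus against cauda, caput against corpus and any region, 4400, 1481 and 2140 were highest in caput, corpus and cauda, and 23 list tests were called, the added one being the interferon list for caput against cauda (adjusted p = 0.042). Depth limits Prm1 between corpus and cauda, where both regions had too few reads for a fold. The named calls lost most often included Tnp2, Trac, Prm1 and Ptprc; the cause was not tested. With 3 residual degrees of freedom, a missed call is no sign of equal expression.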

Other observations

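All tests in this part were chosen after the results were seen, except those on GC content. Gene families were formed by symbol stem, after the data were seen, and 160 with at least 10 tested members gave 480 camera tests, of which 30 were called; each adjusted p was 0.909 with an estimated correlation. WAP-domain genes (Wfdc), which encode small protease inhibitors, were lower in caput than cauda for 14 of 15 members and higher for 1, median -4.43 (camera adjusted p = 4.58e-05), with Wfdc6b at -6.29 ± 0.09 and Wfdc9 at -5.48 ± 0.1 (adjusted p at most 1.17e-09). Kazal-type inhibitors (Spink) were lower for 9 of 11 and higher for 1, median -3.08 (camera adjusted p = 0.00708), including Spink10 at -5.48 ± 0.11 and Spink5 at -6.35 ± 0.2, which rose from 25.5 ± 5.55 CPM in caput to 2080 ± 331 in cauda. Kallikreins (Klk), serine proteases, were lower in corpus than cauda for 7 of 12, median -1.86 (camera adjusted p = 0.00606), with Klk1b26 at -6.42 ± 0.18 and Klk1b27 at -5.32 ± 0.39. Without corpus 2 the log2 change of Klk1b27 became -6.17. The beta-protocadherins, adhesion proteins of the Pcdhb cluster, were higher in caput than cauda for 15 of 17, median 2.61 (camera adjusted p = 0.000964), Pcdhb17 at 2.76 ± 0.27 and Pcdhb9 at 2.61 ± 0.28. Histone genes (Hist) were lower in caput for 25 of 31, median -1.96 (camera adjusted p = 9.62e-06), Hist1h2bc at -3.22 ± 0.08. None of these medians changed sign under library totals or with the length trend removed, but the Hist median became -1.1 under library totals and the Spink median -1.89 with the length trend removed. Members with near-identical copies share reads, and the clear cell marker list was higher in the more proximal region of each of these comparisons.

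Corpus stood below both neighbours for 964 genes. Among those with at least 10 CPM in caput and in cauda, chosen after their values were seen, Gpx5 fell from 1840 ± 666 CPM in caput to 1.7 ± 0.821 in corpus and stood at 606 ± 2.86 in cauda. Defb18 measured 46.4 ± 8.62, 0.424 ± 0.0453 and 27.1 ± 12.3 CPM along the duct, Krt19, a simple epithelial keratin, 144 ± 18.2, 13.5 ± 3.6 and 552 ± 184, and the gap junction gene Gja1 30.9 ± 13.3, 3.37 ± 0.388 and 62.2 ± 2.02. The calcium-activated chloride channel Ano1 was higher in caput than corpus by 3 ± 0.11 (edgeR adjusted p = 5.87e-08) and lower in corpus than cauda at -3.58 ± 0.12 (adjusted p = 9.69e-08), and Mtap1b, a microtubule-associated protein gene, by 3.59 ± 0.13 and -3.84 ± 0.13. Beyond Crygc, the lens crystallin genes Crybb1 and Cryba4 were singled out after their values were seen, and crystallin genes were not tested as a group. Crybb1 measured 77.2 ± 2.1 CPM in cauda, 0.284 ± 0.243 in corpus and 1.7 ± 1.37 in caput. Cryba4 measured 730 ± 60 CPM in cauda, 1.81 ± 2.24 in corpus and 26.2 ± 15.9 in caput. The transcription factor gene Gata2 measured 142 ± 10.7 CPM in cauda, 1.36 ± 0.0172 in corpus and 0.71 ± 0.299 in caput, lower in corpus than cauda at -6.7 ± 0.18 (adjusted p = 5.98e-08).

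The clear cell markers fell by a median of 3.51 log2 units from caput to cauda while the luminal secretory list took 11.694% and 11.275% of reads in cauda 1 and cauda 2, against 1.656% and 1.926% in caput. More of every other cell type in cauda would lower all their markers in caput, but basal markers had a median of 1.45 in favour of caput. Its 95% bootstrap interval of 0.88 to 2.27 resamples genes and leaves out the spread between libraries. Dilution of cauda clear cells by principal cells, or other cells with the transcripts of the luminal list, or by their RNA, would lower the markers by about the same factor. Of the markers, 11 of 15 lay within 1 log2 unit of the median fall, but the falls ranged from 0.78 to 6.23. The markers stood 0.36 higher in cauda 2 than cauda 1 and 0.19 higher in corpus 2 than corpus 1, against -0.1 to 0.1 and -0.07 to 0.12 for 95% of matched random lists. The luminal share was lower in cauda 2 than cauda 1, as dilution predicts, but higher in corpus 2 than corpus 1 (9.314% against 8.673%), the opposite. Members of the list moved both ways in corpus, however. From corpus 1 to corpus 2, Crisp1 rose from 4.082% to 4.919% of reads and Spink8 fell from 2.144% to 1.852%, so the corpus share does not decide it. Dilution and a real fall per clear cell cannot be told apart here because region and share are confounded. The sort for EGFP should remove other cells, but its purity is not given in the sources used here. Smcp of the sperm list measured 20.25 and 70.99 CPM in cauda 1 and 2, but it varied as widely in corpus 1 and 2, at 0 and 44.7 CPM. Of the other sperm transcripts named by the rule, Odf2 averaged 31.94 CPM in cauda, and Prm1, Prm2 and Tnp2 averaged 0.0545, 1.062 and 0.1145 CPM. The sperm list therefore does not settle whether other cells passed the sort.

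Transcripts abundant in corpus shared a lowest ratio in caput. Of 809 genes with at least 200 CPM in corpus, 52 lay between log2 -4.5 and -3.5 of that level in caput, 0 lay below -5, and the lowest, Npy, stood at 4.39% of its corpus level in TMM-scaled CPM. Corpus material in the caput libraries and low expression by caput clear cells cannot be told apart: of 5600 genes with 20 to 200 CPM in corpus, 2 lay below log2 -5 in caput and 10 in cauda, but the test came from the same data that gave the idea. Reads passed evenly between libraries in sequencing would give cauda-abundant genes the same limit, but 19 of 860 lay below log2 -6 in caput, Smpx at -8.5.

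Most ribosomal protein and oxidative phosphorylation genes (73 of 82 and 58 of 76) were lower in caput than cauda, with medians of -1.99 and -1.06 that became -1.12 and -0.2, with 57 and 37 lower, under library totals. Gene length was tested since both lists are short (medians of 1405 and 1336 bases against 3405 for all tested genes) and since length-matched random lists had a median of -0.54. Removing the length trend left ribosomal proteins at -1.3 (95% bootstrap interval over genes -1.42 to -1.02), so the trend on deposited gene length does not account for all of their fall in these libraries. It left oxidative phosphorylation at -0.41 (-0.56 to -0.19). There length may account for part of the fall and cannot be told apart from other causes because the interval reaches the bound set for it. Both intervals resample the genes of a list as if they were independent, so they leave out the spread between libraries. The deposited length reaches 1239378 bases in the longest class and need not be that of the transcript, so transcript length is not excluded for either list. Removing a trend on GC content left -2.06 and -1.14, which argues against GC content as the cause of either. A difference between regions in these transcripts, or in RNA integrity, was not tested further.

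Lymphocyte markers stood higher in replicate 2 than replicate 1 in every region, by medians of 2.33 in caput, 0.51 in corpus and 1.83 in cauda (log2), and MHC class II genes by 0.87, 0.73 and 0.52. Sperm transcripts stood 2.81 and stromal markers 1.86 higher in caput 2 than caput 1.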
